A study of Mus musculus with 13 samples.

How the data were processed

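Expression was measured on 13 Affymetrix mouse gene arrays hybridised with biotin-labelled cRNA from naive C57BL/6 liver cells. Hepatocytes, Kupffer cells and liver sinusoidal endothelial cells (LSEC) had 3 arrays each and were freshly sorted. Hepatic stellate cells (HSC) were cultured in serum-containing medium for 1 day (2 arrays), 7 days (1 array) or 14 days (1 array). The titles call the arrays biological replicates, except those of 7-day and 14-day HSC. The p-values of the population comparison measure the spread between the replicates so named. In the culture comparison the spread came from all groups, the freshly sorted cells included, with the 7-day and 14-day arrays treated as replicates. Its p-values therefore do not measure the spread between replicate HSC cultures alone. Whether replicates came from separate animals was not given in the sources used here. The number of arrays limits the precision.

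The deposited table gives one summarised intensity per probe set and array on a linear scale, from 10.6 to 28854 over 25194 probe sets. The submitters' processing notes name Affymetrix Expression Console and MAS5 version 5.0 without a role or an order. Background correction, the normalization method and the genome build were not given in the sources used here. Array medians lay between 216.5 and 232.9. MAS5 signal had been anticipated, but the values showed little spread at the low end and came without detection calls, so the summary method remains uncertain. They were used on their linear scale without further normalization in the main analysis. A log2 difference near the low end understates a fold, because a constant was added before taking logs.

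Of the probe sets, 21181 carried a single gene symbol, 1379 carried several and 2634 carried none. The single symbols covered 19537 distinct names, and 21097 of these probe sets matched a gene of the RefSeq table for GRCm38.p6 by Entrez identifier, while 84 did not. That table was used for names and for the order of neighbouring genes alone. Probe sets with several symbols or none were left out of the gene tests. Each gene was represented by its probe set with the highest mean. Genes were kept if their intensity was above the pooled median of 224.5 in at least 2 arrays of the fit, and values were taken as log2(intensity + 83), where 83 is the pooled 20th percentile.

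The populations were compared in R 4.3.3 with limma 3.58.1 on the 11 arrays of the 4 groups hepatocytes, Kupffer cells, LSEC and 1-day HSC. The fit covered 12082 genes with 7 residual degrees of freedom and a prior of 4.87. All 6 pairwise contrasts were adjusted by Benjamini-Hochberg within each contrast. A gene was called higher in a population if its adjusted p was below 0.05 and its log2 difference was at least 1 against each of the other 3. The adjusted p printed for such a gene is the largest of its 3 contrasts. The culture comparison used all 13 arrays and 12369 genes, with the 7-day and 14-day arrays merged and set against the 2 arrays of day 1, 8 residual degrees of freedom and a prior of 4.47. The same threshold of adjusted p and log2 difference was used. The 7-day and 14-day arrays were compared with each other by values alone, since each time had 1 array. All tests were two-sided.

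A set of 41 gene lists, written from textbook knowledge, was tested with camera at a preset correlation of 0.01, for each population against the mean of the other 3 and for the culture comparison. Adjusted p-values of the lists are Benjamini-Hochberg over the lists within a comparison. Lists with at least 5 measured members were tested. An estimated correlation and the rotation test fry were run as alternatives. The overlap of culture calls with population calls was tested by Fisher's exact test.

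Named genes followed a rule. For each population they were the 10 called genes with the largest difference from the nearest other population, and for culture the 10 largest rises and 10 largest falls among genes whose long-culture arrays both lay beyond both day 1 arrays. From each list described, up to 4 called members and up to 2 members that did not pass were named by the size of their difference. In addition, 16 anchor genes were named whatever their result. For day 14 against day 7 the 5 largest rises and 5 largest falls were named. Groups, comparisons, filters, lists, this rule and most alternatives were set before the data were examined. A few alternatives and tests of explanations were chosen after seeing the data and are named as such.

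The fits were tested on simulated data with 200 changed genes. For hepatocytes against each other population, over 12082 genes, 194 genes were recovered at a log2 difference of 1.5, 200 at 2 and 200 at 3, with 0 false calls. In the culture comparison, over 12369 genes, 195 were recovered at 1.5, 198 at 2 and 200 at 3, with 1 false call at 1.5 and 0 at the others. In the hepatocyte simulations Kupffer cells and 1-day HSC had 0 calls, unlike in the real data. The counts show that the fits recover differences placed in simulated data. They do not give the rate of false calls in the real data. The spread between replicate long cultures was not measured, so the simulation cannot test it.

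Alternatives covered the pseudocount, the filter, quantile and percentile scaling, the probe set per gene, the variance model, array weights, the threshold, the call rule, the arrays in the fit and leaving out each array in turn. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. No array was left out of the main analysis.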

Results

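Gene expression was profiled in 4 kinds of mouse liver cell: hepatocytes, the parenchymal cells, Kupffer cells, the resident macrophages, liver sinusoidal endothelial cells (LSEC), and hepatic stellate cells (HSC), the perisinusoidal cells that store retinoids and can become matrix-producing myofibroblasts. Hepatocytes, Kupffer cells and LSEC had 3 arrays each. HSC had 2 arrays after 1 day of culture, 1 after 7 days and 1 after 14 days, and no array of uncultured HSC was measured. Values are probe-set intensities, and errors of intensities are SD. On the log2 scale across probe sets, arrays of the same group correlated at r = 0.9866 to 0.9953, and probe sets are not independent replicates. The 7-day and 14-day arrays correlated at 0.9872.

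The first comparison asked which genes set each liver-resident population apart from the others. In pairs, hepatocytes and Kupffer cells differed most widely, with 1454 genes higher in hepatocytes and 1653 higher in Kupffer cells. LSEC and 1-day HSC differed least, with 633 and 676 genes. Some LSEC genes were read on the 1-day HSC arrays and were low in longer cultures, with median shares of 13.79% and 11.52% of the LSEC level. Whether LSEC RNA on those arrays made the 2 groups look closer was not tested. For each of the 40 genes named by rank in the 4 populations, every array of the population lay above every other of the 11 arrays. The rule picked the widest differences on these same arrays, so this separation is not separate support. The numbers of called members reported for each list were identical when adjusted over the list alone.

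**Figure D1:**
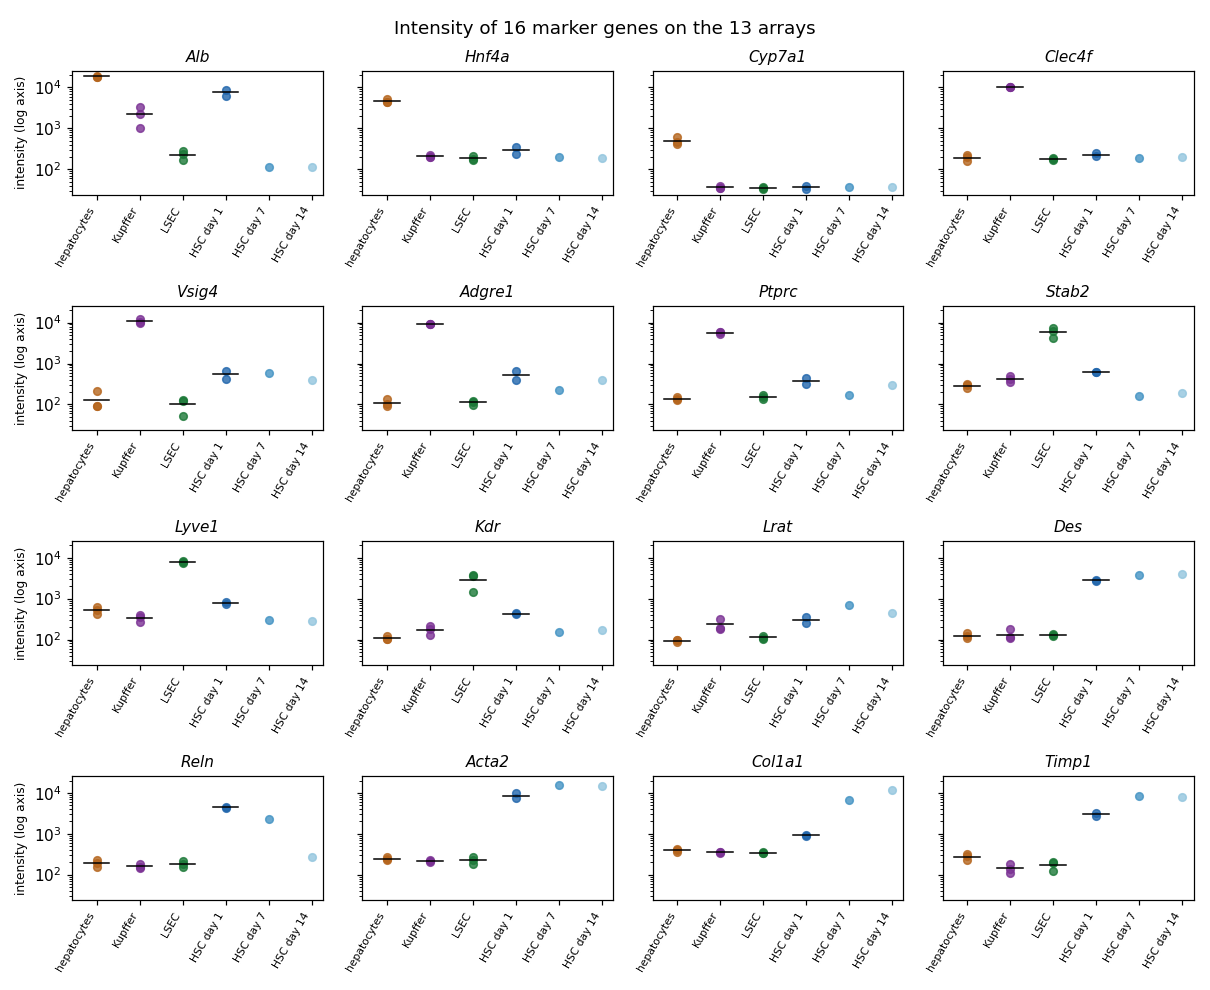
Intensity (log axis) of 16 marker genes on the 13 arrays, by population and days in culture. Each point is 1 array and the black line is the group mean. Alb reads 18570 in hepatocytes and 7570 in 1-day HSC, and Col1a1 reads 11780 after 14 days.

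The genes that stood highest in hepatocytes against the other populations included enzymes of amino acid and drug metabolism and secreted liver proteins. Tat, which degrades tyrosine, averaged 11320 ± 880 (n = 3) in hepatocytes and 134.5 ± 27.5 (n = 3) in Kupffer cells, the nearest population, a log2 difference of 5.72 (SE 0.098, adjusted p = 5.0e-12). The cytochrome P450 gene Cyp2f2 averaged 13990 ± 404, and Hamp, which encodes the iron hormone hepcidin, averaged 10850 ± 941. Their log2 differences from 1-day HSC were 5.71 and 5.64. Next in size were Cdo1 at 5.15, Cyp2c70 at 5.09, C9 at 5.09, the urea cycle enzyme gene Cps1 at 5.09, Igfbp1 at 4.98, Tdo2 at 4.86 and Ces3b at 4.85. In all, 822 genes were higher in hepatocytes than in each other population and 328 were lower. The transcription factor gene Hnf4a averaged 4713 ± 499, a log2 difference of 3.69. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, averaged 502 ± 109 in hepatocytes, a log2 difference of 2.28 (adjusted p = 7.7e-09).

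All 24 measured hepatocyte markers were higher in hepatocytes, among them the fibrinogen chain gene Fgg, Ahsg, Ambp and Serpina1c, with log2 differences from the mean of the other populations of 5.59, 5.47, 5.34 and 5.28 (list adjusted p = 4.0e-16). Of the cytochrome P450 and conjugation genes 22 of 27 were higher, including Cyp3a11 at 5.23 and Ugt2b1 at 5.04 (adjusted p = 2.0e-16), while Fmo1 at 2.04 and Ephx1 at 1.47 did not pass. Bile acid genes were higher for 17 of 19 members, including Cyp7b1 at 4.73 and the uptake transporter gene Slc10a1 at 4.54 (adjusted p = 3.0e-12). Urea and amino acid genes were higher for 20 of 22, including Mat1a at 5.31 (adjusted p = 1.8e-14). With an estimated correlation these lists had adjusted p = 0.23 for the markers and adjusted p = 0.19 for each of the other 3. Complement and coagulation genes were higher for 25 of 38 members and lower for 1, including F2 at 4.95 and C8b at 4.81 (adjusted p = 3.6e-09, and adjusted p = 0.26 with an estimated correlation). Cholesterol synthesis genes were higher for 9 of 20, with Tm7sf2 at 3.13 and Msmo1 at 2.24 (adjusted p = 3.4e-07, and adjusted p = 0.26 with an estimated correlation). Fatty acid oxidation genes were higher for 9 of 17 and lower for 1, with Slc27a2 at 5.24, Fabp1 at 5.11 and the nuclear receptor gene Ppara at 2.53 (adjusted p = 1.5e-05, and adjusted p = 0.19 with an estimated correlation). Of the mesothelial list, which shares simple epithelial keratins with hepatocytes, 3 of 5 were higher, Krt18 at 5.07, Krt8 at 4.33 and Cdh1 at 3.60 (adjusted p = 0.025, and adjusted p = 0.23 with an estimated correlation). Retinoid genes were higher for 7 of 27, with Rbp4 at 5.23, Rarres2 at 3.96 and Aldh1a1 at 3.87 (adjusted p = 0.029, and adjusted p = 0.36 with an estimated correlation).

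Albumin transcripts were abundant on arrays beyond those of hepatocytes, and their source on the 1-day HSC arrays is taken up under the other observations. Alb averaged 18570 ± 100 in hepatocytes (n = 3), 7570 ± 1820 in 1-day HSC (n = 2), 2231 ± 1170 in Kupffer cells (n = 3) and 227.9 ± 54 in LSEC (n = 3). On the 3 Kupffer cell arrays Alb read 3374, 1027 and 2292, and Serpina1c read 295.9, 82.55 and 219.9 in the same order. The source of Alb on the Kupffer cell arrays was not tested. The log2 difference of hepatocytes from 1-day HSC was 1.31 (SE 0.347, adjusted p = 0.0052), and without HSC day 1 replicate 2 the difference was 1.06 and did not pass (adjusted p = 0.061).

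The genes that set Kupffer cells apart by the widest margin included macrophage receptors and a class II gene. Adgre4, a macrophage adhesion receptor of the F4/80 family, averaged 4312 ± 154 (n = 3) against 42.49 ± 6.21 in hepatocytes (n = 3), a log2 difference of 5.13 (SE 0.07, adjusted p = 1.7e-12). The Kupffer cell lectin gene Clec4f averaged 10280 ± 163 and was higher by 5.06, and Cd5l, a secreted macrophage protein, averaged 11980 ± 620 and was higher by 5.03. P2ry13 and the Fc receptor gene Fcgr4 averaged 7901 ± 618 and 6674 ± 553. The chemokine gene Cxcl13 was higher by 4.96, the haemoglobin scavenger receptor gene Cd163 by 4.83, Bank1 by 4.81, the class II gene H2-Aa by 4.69 and Gpr65 by 4.45. In all, 788 genes were higher in Kupffer cells and 275 were lower. Among the anchor genes, Vsig4 averaged 10670 ± 1250 (log2 difference 4.12), Adgre1 9114 ± 154 (3.96) and the leukocyte gene Ptprc 5600 ± 361 (3.65).

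Of the Kupffer cell markers 21 of 22 were higher (adjusted p = 2.5e-14, and adjusted p = 0.16 with an estimated correlation), while Hmox1, at 0.15 above the mean of the other populations, did not pass. Class II and costimulation genes were higher for 13 of 15 members, including Cd86 at 4.87 and the invariant chain gene Cd74 at 4.60 (adjusted p = 6.8e-11, and adjusted p = 0.039 with an estimated correlation). Innate sensing genes were higher for 17 of 30, with Ly86 at 5.20, Cd180 at 4.46, the inflammasome gene Nlrp3 at 4.31 and Tlr7 at 4.01 (adjusted p = 7.0e-14, and adjusted p = 0.039 with an estimated correlation), whereas Tlr4 at 1.91 did not pass. Class I processing genes were higher for 3 of 14, namely H2-M3 at 2.02 and the immunoproteasome genes Psmb8 at 1.76 and Psmb9 at 1.55 (adjusted p = 0.00014, and adjusted p = 0.039 with an estimated correlation). Interferon-stimulated genes were higher for 7 of 24, with Oas2 at 4.07 and Ifit2 at 3.31 (adjusted p = 8.4e-06, and adjusted p = 0.36 with an estimated correlation). Immediate-early genes, which cell dissociation can induce, were higher for 8 of 28 and lower for 1, with Fosb at 4.45, Fos at 3.89 and Nr4a1 at 3.14 (adjusted p = 6.1e-06, and adjusted p = 0.36 with an estimated correlation). Scavenger receptor genes were higher for 8 of 21, with Timd4 at 4.11 and Msr1 at 4.08 (adjusted p = 0.0044, and adjusted p = 0.36 with an estimated correlation). Markers of B and plasma cells were higher on the Kupffer cell arrays for 3 of 7 members, Cd79b at 2.46, Cd22 at 1.96 and Blnk at 1.40 (adjusted p = 0.0034, and adjusted p = 0.36 with an estimated correlation). The T and NK cell list was higher for 1 of 5, Klrk1 at 2.06 (adjusted p = 0.048, and adjusted p = 0.36 with an estimated correlation), and did not pass after quantile normalization (adjusted p = 0.051). Monocyte and dendritic cell genes were higher for 3 of 7, including Clec9a at 3.18 and Batf3 at 1.72, and the list did not pass (adjusted p = 0.069). Blnk did not reach the minimum difference with the pooled median as pseudocount, at 0.85 above the nearest population.

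In LSEC the widest margin was that of the tight junction gene Cldn5, which averaged 6441 ± 1630 (n = 3) against 396.7 ± 43.6 in 1-day HSC (n = 2), a log2 difference of 3.74 (SE 0.188, adjusted p = 1.3e-08). Rasip1, which acts in vessel lumen formation, was higher by 3.27 and Oit3 by 3.25 (SE 0.279). The hyaluronan receptor genes Lyve1 and Stab2 averaged 7914 ± 433 and 6008 ± 1680 and were higher by 3.23 and 3.07. The coagulation factor gene F8 averaged 5535 ± 1490 and was higher by 2.94. St8sia4 was higher by 3.16, Plekhg1 by 3.12, Cyyr1 by 2.88 and Sox7 by 2.82. Kdr, the main receptor for VEGF, averaged 2896 ± 1280 and was higher by 2.42 (adjusted p = 4.7e-05). In all, 284 genes were higher in LSEC and 49 were lower, and for each gene named here the nearest population was 1-day HSC. For each of them LSEC replicate 3 read lowest of the LSEC arrays. Kdr read 3747, 3519 and 1422 in replicates 1 to 3, and Oit3 read 6156, 6539 and 2703. Without LSEC replicate 3 the count was 337, and the cause was not tested. LSEC RNA on the 1-day HSC arrays would also lower the differences from 1-day HSC and the count, and it was not tested.

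Of the LSEC markers 14 of 26 were higher, including the angiopoietin receptor gene Tek at 3.77 and Egfl7 at 3.74 above the mean of the other populations (adjusted p = 1.5e-10, and adjusted p = 0.28 with an estimated correlation), while Emcn at 3.18 and Eng at 2.95 did not pass against each population. Large-vessel endothelial genes were higher for 5 of 11, with Edn1 at 3.96, Sox17 at 2.55 and Cd34 at 2.45 (adjusted p = 0.013, and adjusted p = 0.30 with an estimated correlation). Among scavenger and endocytic receptors 4 of 21 were higher and 1 was lower, with Fcgr2b at 3.17 and Lrp1 at -3.20. The list did not pass (adjusted p = 0.65), and its median lay below 0 while its mean lay above 0. Cytokine and growth factor genes were higher for 3 of 27, namely Angpt2 at 3.66, Bmp6 at 3.20 and the Notch ligand gene Dll4 at 1.81. In that list Igf1 was lower at -3.46, and the list did not pass (adjusted p = 0.17). The retinoid list was lower with none of its 27 genes called (adjusted p = 0.040, and adjusted p = 0.39 with an estimated correlation), and did not pass after quantile normalization (adjusted p = 0.054). Immediate-early genes were lower for 3 of 28, Gadd45g at -2.29, Egr1 at -2.23 and Hspa1a at -1.41 (adjusted p = 3.0e-06, and adjusted p = 0.29 with an estimated correlation). Against the nearest population, Egr1 did not reach the minimum difference without LSEC replicate 3 (-0.84), nor Hspa1a without LSEC replicate 2 (-0.96) or with the pooled median as pseudocount (-0.91).

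The genes that set 1-day HSC apart by the widest margin included smooth muscle genes, receptors and secreted factors. Serpinb2, a plasminogen activator inhibitor, averaged 5452 ± 692 (n = 2) against 96.46 ± 21.8 in LSEC (n = 3), a log2 difference of 4.95 (SE 0.116, adjusted p = 4.1e-11). The smooth muscle genes Tagln and Acta2 averaged 7215 ± 733 and 8603 ± 1620 and were higher by 4.84 and 4.72. Robo2, a receptor for Slit proteins, was higher by 4.77, the prostaglandin synthase gene Ptgs2 by 4.73 and the chemokine gene Cxcl12 by 4.70. Bmp10 averaged 4030 ± 1660 and was higher by 4.63, followed by the osteoprotegerin gene Tnfrsf11b at 4.55, the YAP target gene Ankrd1 at 4.54 and the sphingosine phosphate receptor gene S1pr3 at 4.48. Of the anchor genes, Reln averaged 4464 ± 188 and was higher by 4.05, and Timp1, an inhibitor of matrix proteases, was higher by 3.08. The intermediate filament gene Des averaged 2819 ± 159 in 1-day HSC and 132.6 ± 39.4 in Kupffer cells (adjusted p = 4.7e-10). Col1a1 averaged 919.8 ± 21.3 and was higher by 1.08 (SE 0.081). Lrat, which makes retinyl esters, read 305.4 ± 68 in 1-day HSC and 233.6 ± 77.6 in Kupffer cells and did not pass (log2 difference 0.31, adjusted p = 0.11). In all, 312 genes were higher in 1-day HSC and 34 were lower. With a single HSC array the count was 207 without HSC day 1 replicate 1 and 169 without HSC day 1 replicate 2. HSC were cultured and the others freshly sorted, so population and culture cannot be separated here.

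Stellate cell markers were higher for 12 of 21 members, with the proteoglycan gene Dcn at 4.24 and Reln at 4.13 above the mean of the other populations (adjusted p = 1.4e-11, and adjusted p = 0.040 with an estimated correlation), while Hgf at 1.66 did not pass. Myofibroblast activation genes were higher for 12 of 20, with Tnc at 5.53 and Thbs1 at 4.87 (adjusted p = 2.4e-13, and adjusted p = 0.040 with an estimated correlation). Collagen and matrix genes were higher for 14 of 27, with Bgn at 3.55, Lamb1 at 2.69 and Nid1 at 2.68 (adjusted p = 1.7e-12, and adjusted p = 0.040 with an estimated correlation). Sparc at 3.02 and Fn1 at 2.68 did not pass against each population, although both were higher than the mean of the others. Collagen processing genes were higher for 7 of 16, with the cross-linking enzyme gene Lox at 4.53 and Plod2 at 2.99 (adjusted p = 0.00028, and adjusted p = 0.040 with an estimated correlation). Contractile genes were higher for 7 of 21, with Myl9 at 3.23 and Cnn2 at 3.02 (adjusted p = 3.1e-13, and adjusted p = 0.061 with an estimated correlation). Genes of the PDGF, hedgehog and YAP axis were higher for 8 of 19, with Ccn2 at 3.68 (adjusted p = 4.2e-06, and adjusted p = 0.069 with an estimated correlation). Lists of other cell types passed on these arrays as well. Vascular smooth muscle genes were higher for 1 of 9, Rgs5 at 2.63 (adjusted p = 0.00088, and adjusted p = 0.16 with an estimated correlation). Portal fibroblast genes were higher for 3 of 11, Dpt at 2.88, Fbln2 at 2.29 and Mfap5 at 2.24 (adjusted p = 0.020, and adjusted p = 0.28 with an estimated correlation). Retinoid genes were higher for 0 of 27, and the list did not pass (adjusted p = 0.17), with Dhrs3 at -1.52 and Rarb at 1.32. Interferon-stimulated genes were lower for 3 of 24, Oasl1 at -1.96, Rsad2 at -1.93 and Usp18 at -1.77 (adjusted p = 2.6e-06, and adjusted p = 0.28 with an estimated correlation).

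The second comparison asked how HSC differed after 7 or 14 days of culture from HSC after 1 day, the labels calling the cells culture-activated. The largest rises included genes of smooth muscle and of the matrix. Cnn1, a calponin of smooth muscle, read 157.7 and 160.3 on the day 1 arrays, 5888 at day 7 and 6146 at day 14, a log2 difference of 4.66 (SE 0.086, adjusted p = 4.4e-12). The aggrecanase gene Adamts5 rose by 4.16, the hyaluronidase gene Cemip by 3.98, the growth factor gene Vegfd by 3.96 and the calcium-binding gene S100a6 by 3.94. Actg2, a smooth muscle actin, rose by 3.72, Lurap1l by 3.64, Tmem45a by 3.60 and the guidance ligand gene Slit3 by 3.40. The proteoglycan gene Ogn read 160.5 on average at day 1, 2949 at day 7 and 3379 at day 14. Col1a1 rose by 3.17 (SE 0.179, adjusted p = 5.3e-08), to 6807 at day 7 and 11780 at day 14, and Timp1 by 1.46. Acta2 read 15220 and 14600 in the longer cultures and did not reach the minimum difference (0.80, adjusted p = 0.00067). Lrat likewise did not reach it, at 704.7 and 456.8 (0.76, adjusted p = 0.0092), nor did Des, at 3769 and 4019 (adjusted p = 0.017). In all, 683 genes rose and 528 fell between 1 day and the longer cultures. The balance turned without the day 7 array, with 560 rises and 694 falls, and without a minimum difference, with 2316 and 3122.

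**Figure D2:**
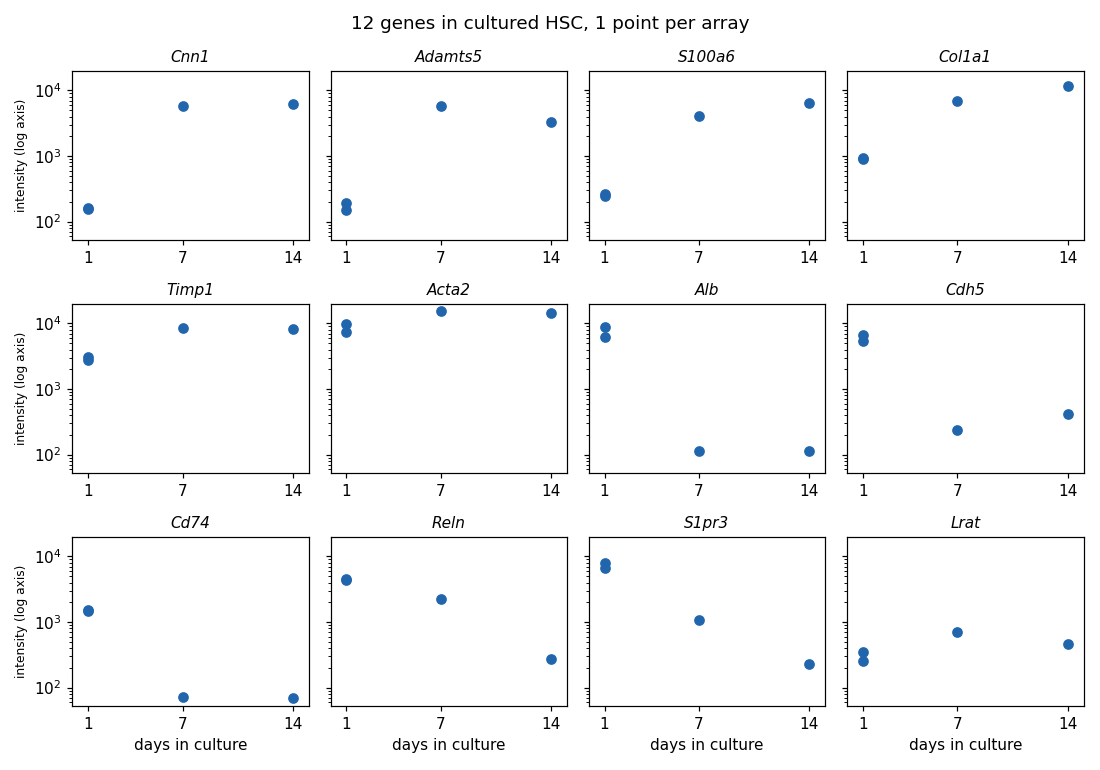
Intensity (log axis) of 12 genes in HSC against days in culture, with 1 point per array and 2 arrays at day 1. Col1a1 reads 11780 at day 14, and Alb reads 8855 and 6285 at day 1 and 112.8 at day 14.

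Collagen and matrix genes rose for 16 of 28 members, with Col1a2 at 3.04 (2.40 without the day 14 array) and Fbln2 at 2.77 (adjusted p = 2.7e-14, and adjusted p = 0.080 with an estimated correlation), while Eln at 0.95 and Col6a2 at 0.90 did not pass. Collagen processing genes rose for 11 of 17, with the protease genes Tll1 at 2.30 and Bmp1 at 1.89 and the enhancer gene Pcolce at 2.21 (adjusted p = 1.1e-09, and adjusted p = 0.0043 with an estimated correlation). Matrix proteases and their inhibitors rose for 10 of 19, with Timp2 at 2.01 and the stromelysin gene Mmp3 at 1.92 (adjusted p = 7.4e-05, and adjusted p = 0.092 with an estimated correlation). Myofibroblast activation genes rose for 9 of 20, with Thbs2 at 3.20 (adjusted p = 3.5e-05, and adjusted p = 0.23 with an estimated correlation). Contractile genes rose for 7 of 23, with the myosin gene Myh11 at 2.71 (adjusted p = 5.0e-06, and adjusted p = 0.23 with an estimated correlation). Cell cycle genes rose for 19 of 30, with the cyclin gene Ccna2 at 2.46, Cdk1 at 2.34, Mki67 at 2.15 and Bub1 at 2.09 (adjusted p = 3.7e-11, and adjusted p = 0.44 with an estimated correlation). Cholesterol synthesis genes rose for 8 of 20, with Idi1 at 1.57, Msmo1 at 1.41 and Cyp51 at 1.38 (adjusted p = 4.4e-07, and adjusted p = 0.42 with an estimated correlation). Vascular smooth muscle genes rose for 6 of 11 and fell for 1, with Itga8 at 2.45 (adjusted p = 7.4e-05, and adjusted p = 0.092 with an estimated correlation). Portal fibroblast genes rose for 3 of 12 and fell for 1, with Thy1 at 2.89, Mfap5 at 1.90 and Dpt at -2.44 (adjusted p = 0.023, and adjusted p = 0.44 with an estimated correlation).

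Genes that fell included stellate, endothelial and hepatocyte genes. For hepatocyte and endothelial genes, here and in the lists below, and for Cd74, a fall need not be a change in HSC. RNA of other cells may have been on the day 1 arrays, a point taken up under the other observations. Alb fell most, from 8855 and 6285 to 114.2 and 112.8 (log2 difference -5.26, SE 0.371, adjusted p = 4.1e-07). The chemokine gene Cxcl2 fell, with a log2 difference of -3.98, as did the endothelial cadherin gene Cdh5 (-3.91), Prg4 (-3.75), Adgrl4 (-3.69) and S1pr3 (-3.62). Cd74, Serpina1c and Robo2 also fell (-3.36, -3.36 and -3.08). The longer cultures differed for some of these: S1pr3 read 1070 at day 7 and 232.8 at day 14, and Robo2 read 1051 and 352. Without the day 14 array their differences were -2.69 and -2.39. Cdh5 also averaged 9635 ± 456 in Kupffer cells and 13860 ± 490 in LSEC. Cd74 averaged 13200 ± 1270 in Kupffer cells, and the source of its day 1 signal (1486 and 1505) was not tested. Cyp2e1 read 2320 ± 1440 at day 1, 64.28 at day 7 and 76.91 at day 14. Stab2 and Lyve1 fell (-1.46 and -1.17), and Lyve1 did not reach the minimum difference with the pooled median as pseudocount (-0.93). Kdr fell by 1.09 (adjusted p = 0.017) and did not pass without HSC day 1 replicate 1 (adjusted p = 0.055), without HSC day 1 replicate 2 (adjusted p = 0.083), without the day 7 array (adjusted p = 0.070) or with the pooled median as pseudocount (log2 difference -0.77). Levels of Vsig4, Adgre1, Ptprc, Clec4f and Hnf4a did not pass, with log2 differences of -0.10, -0.62, -0.54, -0.19 and -0.42. Reln read 2270 at day 7 and 276.6 at day 14 (adjusted p = 0.0048). It did not reach the minimum difference without the day 14 array (-0.95) and did not pass in a fit of the 4 HSC arrays alone (adjusted p = 0.089).

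Hepatocyte markers fell for 17 of 24 members (adjusted p = 4.4e-07, and adjusted p = 0.46 with an estimated correlation), including the retinol carrier gene Rbp4 at -2.50. LSEC markers fell for 15 of 26, including Fcgr2b at -2.63, Bmp2 at -2.53 (-1.89 without the day 14 array) and Pecam1 at -2.35 (adjusted p = 6.8e-06, and adjusted p = 0.44 with an estimated correlation). Chemokine genes fell for 8 of 21, with Cxcl12 at -2.71 and Cxcl16 at -1.90 (adjusted p = 0.0031, and adjusted p = 0.43 with an estimated correlation). Antioxidant genes controlled by NRF2 fell for 9 of 16 and rose for 1, with the cystine transporter gene Slc7a11 at -2.94, Gclc at -1.83 and Srxn1 at -1.73 (adjusted p = 0.0016, and adjusted p = 0.54 with an estimated correlation). Stellate cell markers fell for 5 of 21 and rose for 1, with Hhip at -2.13, Rgs5 at -2.11 and Vipr1 at -1.87 (-0.36 at its other probe set), and the list did not pass (adjusted p = 0.14). Retinoid genes rose for 6 of 28 and fell for 1, with the retinaldehyde dehydrogenase gene Aldh1a1 at 2.62, Dhrs3 at 2.54 and the receptor gene Rarb at 2.05, and the list did not pass (adjusted p = 0.15).

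**Figure D3:**
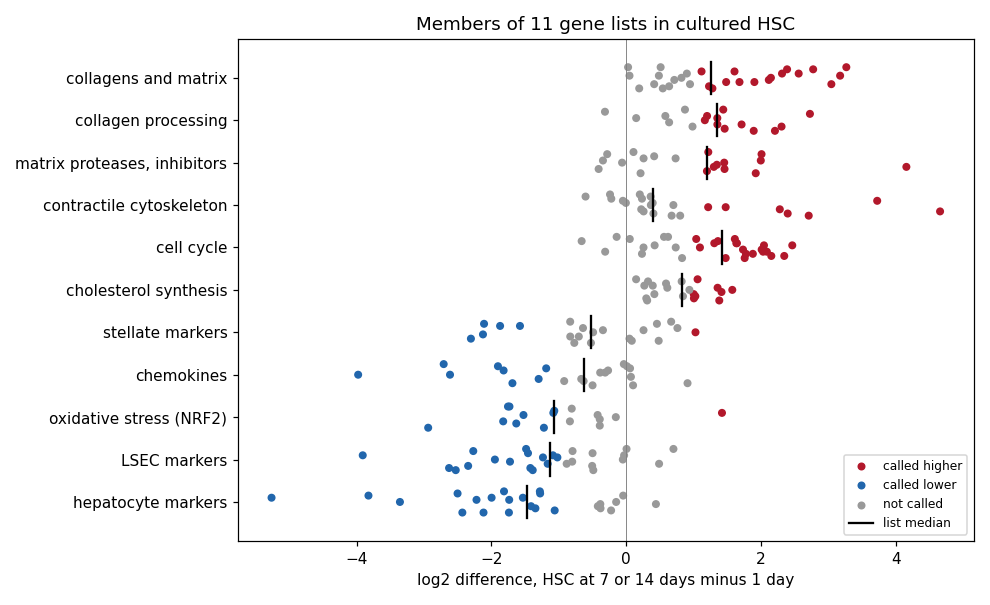
Log2 difference between HSC at 7 or 14 days and HSC at 1 day for the measured members of 11 gene lists. Each point is a gene, coloured red if called higher, blue if called lower and grey if not called, and the black line is the list median. Collagen and matrix genes were called higher for 16 of 28 members and hepatocyte markers called lower for 17 of 24.

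Of the 528 genes that fell, 142 were among those called higher in hepatocytes, Kupffer cells or LSEC, and 386 were not. Of the 683 genes that rose, 141 were among them and 542 were not. The expected counts were taken over the 12082 genes tested in both comparisons, which hold all 528 falls but 543 of the rises. Genes called in hepatocytes made up 67 of the falls against 35.9 expected (Fisher's exact test, adjusted p = 1.1e-06) and 49 of these rises against 36.9 (adjusted p = 0.051). Genes called in LSEC made up 44 of the falls against 12.4 (adjusted p = 4.2e-13) and 31 of these rises against 12.8 (adjusted p = 9.8e-06). Genes called in Kupffer cells made up 31 of the falls against 34.4 (adjusted p = 0.59) and 61 of these rises against 35.4 (adjusted p = 3.3e-05). Genes called in 1-day HSC made up 58 of these rises and 55 of the falls. The day 1 arrays entered both comparisons, so the expected counts, which assume independent arrays, are not the counts that no link would give. For 1-day HSC no excess is read from the overlap, and for the other populations the p values carry the same limit.

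Day 14 was set beside day 7 by values alone. Sparcl1 read 207 at day 7 and 1573 at day 14, a log2 difference of 2.51, and Angptl7, the calcification inhibitor gene Mgp, Serpina3n and Shisa3 were higher at day 14 by 2.40, 2.29, 2.23 and 2.06. Plvap, of endothelial diaphragms, read 3352 at day 7 and 403 at day 14 (-2.82). Bmp10 at -2.81, Hsd11b1 at -2.75, Reln at -2.71 and Cxcl14 at -2.55 were also lower at day 14. All 30 measured cell cycle genes were lower, with a median of -0.67 against -0.117 to 0.039 for the central 95% of 10000 random lists matched on expression. The stellate cell markers had a median of -0.31 (against -0.124 to 0.058), immediate-early genes -0.24 (against -0.174 to 0.04), retinoid genes -0.19 (against -0.139 to 0.039) and the 6 platelet genes -0.25 (against -0.21 to 0.128). Collagen and matrix genes had a median of 0.15 (against -0.144 to 0.037), portal fibroblast genes 0.28 (against -0.147 to 0.077), mesothelial genes 0.27 (against -0.206 to 0.102) and scavenger receptor genes 0.06 (against -0.182 to 0.054). The medians of the other lists lay inside their ranges. These ranges cover only which genes were drawn, not variation between cultures or correlation within a list (0.71 for the cell cycle list in the culture comparison). With 1 array at each time, none of these differences is a test of time in culture. In all, 71 genes were at least 1 higher on the log2 scale at day 14 and 120 at least 1 lower. Log2 differences between these arrays had an SD of 0.311, and those between the 2 arrays of day 1 an SD of 0.199.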

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

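The tests of probe sets without a gene name were chosen only after the culture comparison had been seen. Among probe sets that carry no gene symbol, which the gene comparisons do not use, 31 were higher in HSC after 7 or 14 days than after 1 day. They are given here as a signal above the day 1 level in data outside the gene comparisons, not as an excess. They were 2.29% of the 1351 such probe sets tested in limma, against 5.52% of the genes, and 47 were lower (3.48%, against 4.27% of the genes). An unadjusted p below 0.05 was found for 462 of them. Among 830 probe sets with several symbols, 26 were higher and 26 lower. The sources used here do not name these probe sets, and no explanation was tested for them.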

How the results depend on the processing

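Added after seeing the data were a pseudocount of 0 and counts without genes called in another population. The other alternatives were planned. Of the values for single genes, 9807 stayed the same, 237 passed anew, 41 no longer passed, 15 moved and 11 reversed. For calls, the same means the same side of the threshold and, for called genes, the same direction. Moved values have no threshold. Of these, 3 were other probe sets, judged by a fixed log2 difference. The rest were day 14 against day 7, judged by 1 SD of those differences over all genes. All 11 reversed values were of genes not called in the main analysis, where at least 1 other population read higher. They passed under a call against the mean of the other populations, whose construction averages over the nearest one. These were in hepatocytes C4b (2.30) and Pdk4 (1.42), in LSEC Cd9 (1.02) and Thbd (1.00), and in 1-day HSC Sparc (3.02), Fn1 (2.68), Axl (2.62), Cd44 (2.23), Tgfbi (2.08), Ccl7 (1.33) and Tgfbr3 (1.32). That rule also gave 1249 genes in Kupffer cells, 726 in LSEC and 813 in 1-day HSC. Without a minimum difference, which admits smaller changes by construction, the counts were 1920 in hepatocytes, 1974 in Kupffer cells, 1339 in LSEC and 1292 in 1-day HSC, and 2316 rises and 3122 falls in culture. With the pooled median as pseudocount, which shrinks differences by construction, 324 genes fell in culture. Day 14 against day 7 gave 191 genes in the main analysis, 294 with a pseudocount of 1 and 127 with the pooled median. With an estimated correlation 8 list tests passed, against 106 in the main analysis, and the cause was not tested. They were class II, class I and innate sensing in Kupffer cells, the stellate, myofibroblast, matrix and collagen processing lists in 1-day HSC, and collagen processing in culture.

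Leaving out each array in turn gave 795 to 847 genes in hepatocytes, 780 to 803 in Kupffer cells, 263 to 337 in LSEC and 169 to 317 in 1-day HSC, with 207 and 169 where a single HSC array was left and assumed to vary like the other groups. In culture it gave 560 to 717 rises and 461 to 694 falls. The share of rises among culture calls was 56.4%, 59.3% after quantile normalization, 62.1% after scaling to the 75th percentile and 44.7% without the day 7 array, and the cause was not tested. Replicate numbers gave no sign of pairing: residuals of the same number correlated at -0.111 to 0.111 and of different numbers at -0.125 to 0.132. This cannot show whether arrays of the same number shared an animal or a day. Residuals of the 2 HSC arrays of day 1 mirror each other by construction. With the number as a block the counts were 817, 788, 292 and 308, of which 814, 785, 284 and 306 were shared with the main calls. With a pseudocount of 0, 889 genes rose and 792 fell. Without genes called in another population, 542 rose and 386 fell. The 4 HSC arrays alone gave 654 and 496 with 2 residual degrees of freedom. The alternative without cross-hybridising probe set suffixes could not be run, since the identifiers are numeric. Values near the background limit how small a fold can be measured.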

Other observations

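The 4 counts of other splits of the arrays were planned, and the tests of hepatocyte transcripts and of epidermal genes were chosen only after the result was seen.

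In 1-day HSC, genes of TGF-beta signalling were higher for 7 of 25 members, with Inhba, an activin subunit gene, at 4.62 and the matrix gene Thbs1 at 4.87 above the mean of the other populations (adjusted p = 1.1e-05, and adjusted p = 0.069 with an estimated correlation). Growth factor and cytokine genes were higher for 5 of 27, with the macrophage growth factor gene Csf1 at 3.65, the Wnt enhancer gene Rspo3 at 3.26 and Jag1 at 2.27, and the list did not pass (adjusted p = 0.25). In Kupffer cells the same list was higher for 7 of 27 and lower for 2, with Il1a at 4.32, Il1b at 4.05 and Tnf at 3.56, and it did not pass (adjusted p = 0.88), with a median below 0 and a mean above 0. Kupffer cell chemokine genes were higher for 7 of 21, with Ccl3 at 4.59, Ccl6 at 4.02 and Ccl24 at 3.56, and the list did not pass (adjusted p = 0.065).

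In longer HSC cultures, cytokine and growth factor genes rose for 6 of 29 and fell for 6, with Il6 at 2.31 and the receptor ligand gene Gas6 at 2.29, and the list did not pass (adjusted p = 0.66). TGF-beta genes rose for 5 of 25 and fell for 2, with the latent binding protein genes Ltbp1 at 1.93 and Ltbp2 at 1.82 and Tgfbi at -2.62, and the list did not pass (adjusted p = 0.12). Immediate-early genes rose for 6 of 28 and fell for 2, with Nr4a1 at 1.98, Myc at -1.59 and Nfkbia at -1.43, and the list did not pass (adjusted p = 0.15).

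The role of chance was tested with 100 splits of the 11 arrays into groups of the real sizes, the real one included. As many called genes came from 1 split for hepatocytes (822 genes, highest other 807), from 3 for Kupffer cells (788 genes, highest other 803), from 3 for LSEC (284 genes, highest other 846) and from 1 for 1-day HSC (312 genes, highest other 246). For each population the share of such splits was under 0.05. Groups that mixed populations gave no calls, so the splits show that the populations differ. They cannot exclude chance for the size of a count. The 846 genes came from a split whose LSEC group held only hepatocyte arrays. The 803 came from one whose Kupffer cell group stayed whole. In each of the 10 groups with any call in the other splits, the arrays all came from a single real population, while 13 other groups from a single population gave no call.

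Of the 50 most abundant genes called in each population, 39 for hepatocytes, 40 for LSEC and 18 for Kupffer cells read higher on both 1-day HSC arrays than on both later ones. Of the hepatocyte genes, 35 were low in LSEC and in long-cultured HSC, with median shares of the hepatocyte level of 8.6% on day 1 array 1 and 2.27% on array 2. For LSEC, 14 genes low in hepatocytes and long-cultured HSC had 13.79% and 11.52% of the LSEC level. For Kupffer cells, 17 genes low in LSEC and long-cultured HSC had 0.76% and 2.52% of the Kupffer cell level, the higher share on array 2. By the mean share of both arrays, 5 of the 35 lay more than 5 times off the median of 5.43%. These were Alb at 40.4%, and Cyp2f2, Tat, Hamp and Cps1 at 0.52%, 0.32%, 0.61% and 0.45%. Within each array 5 and 3 did so. The low shares argue against hepatocyte RNA in one fixed ratio to the fresh hepatocyte arrays as the only source. The argument is weaker on array 2, where only Tat and Hamp lay below the bound and Alb, at 33.44%, lay above it. It does not bear on hepatocyte RNA whose make-up differed from that of fresh hepatocytes. Whether intensity stays linear at the level of Alb was not tested, and the bound was set after the shares were seen. The median log2 ratio of array 1 to array 2 over the 35 genes was 1.11, outside the -0.081 to 0.044 of random sets. That ratio restates the shares already seen for these genes and is not separate support. A hepatocyte source whose amount differed between the arrays may account for part of the pattern. Expression by HSC that is lost in culture stays open and untested, as no uncultured HSC were measured, and no explanation was tested for the LSEC genes.

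Some genes of epidermal differentiation and of the S100 family rose in long-cultured HSC, and they were chosen after their values were seen: S100a6 by 3.94, Lce1h by 3.11, Kprp by 2.77, Ivl by 2.77, Crct1 by 2.73, S100a4 by 2.69, Sprr1a by 1.87 and S100a1 by 1.70. They are 8 of 60 measured genes between S100a1 and S100a10 on chromosome 3, of which 21 passed the filter, and Sprr1a did not pass without HSC day 1 replicate 2 (adjusted p = 0.054) or in the 4 HSC arrays alone (adjusted p = 0.078), nor reach the minimum difference without the day 7 array (0.95). Keratinocytes in the culture are argued against by the median log2 difference of 0 over 21 measured keratinocyte markers, with none above 0.55, 2 above the filter at day 1 and the highest reading 396 (Perp), Krt14 reading 139.3 and 119.9. Other cells in the culture, such as mesothelial cells, were not tested as a source of these rises. Chance clustering of calls stays open: over all measured genes without the filter, a window of 20 neighbours as full as the region's fullest, with 5 calls, arose in a share of 0.89 of 1000 shuffles, and an earlier scan of the filtered genes (0.013) is not relied on, as the filter admits low genes partly because they rose. Hybridisation shared between related genes could not be tested without probe sequences, and a change in HSC themselves may account for the rises but stays untested.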
